A study of Mus musculus with 6 samples.

How the data were processed

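Single cells from 6 tumours were profiled by droplet sequencing of RNA 3' ends (10x Genomics 3' v3.1 chemistry), 1 library per tumour. The tumours grew from MOC1, a mouse oral squamous carcinoma line, in the flank of C57BL/6 mice. Each mouse received antisense oligonucleotides (ASOs, short nucleic acids that lower a target RNA) for 18 days, either control ASOs (3 libraries) or ASOs against Smyd3 (3 libraries). The tumours were then resected and dissociated. The labels report 2 NextSeq runs and tie no library to a run, so no sequencing batch could be entered in a model.

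The deposited matrices hold whole-number UMI counts per gene and cell barcode, per the file headers. The submitters' processing notes name Cell Ranger 7.0.0, STAR 2.7.2a, bcl2fastq 2.20.0 and genome build mm10, without their roles. Whether intronic reads were counted is not given in the sources used here. The matrices list 32285 genes with Ensembl identifiers and symbols, and 26926 barcodes. The UMI totals of the libraries were 49119571, 34323332 and 54551408 for control replicates 1, 2 and 3, and 42327350, 44938336 and 51455941 for Smyd3 ASO replicates 1, 2 and 3. Coordinates come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, which held 32158 of the gene identifiers. No gene was left out for sharing reads with a related copy, and the overlap of reads between gene family members was not examined.

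Barcodes with under 200 detected genes (2112 barcodes) or over 15% mitochondrial UMIs (1273 barcodes) were left out, which kept 23727. Doublets were scored with scrublet in scanpy 1.11.5 (python 3.11.15). Its automatic threshold marked 33 cells (0.139%), too few to be of use, so in each library the highest scores were called up to a rate of 0.8% per 1000 barcodes. This rate removed 883 cells (3.72%) and left 22844. Counts were scaled to 10000 per cell and log transformed. Leiden clusters at resolution 1 were made from 2000 variable genes, 30 principal components and 15 neighbours. A cluster was named after the class with the highest mean log2 fold of its fixed markers over the other clusters, and is called "-like" for that reason. A name needed at least 3 markers raised by 1 log2 unit, a mean of at least 0.25, and no other class with more markers among the top 10 genes. Clusters with markers of 2 classes were divided once if they held at least 100 cells, and those still mixed were left unnamed. Clusters of low UMI count were left unnamed only if fewer than 2 markers of their class were among the top 10 genes, so cells of low depth remain in named classes. Unnamed cells made up 3.67% ± 0.80 of control cells and 3.05% ± 0.31 of Smyd3 ASO cells (SD, n = 3 each). The naming thresholds, the division of mixed clusters and the doublet rate were set after the data were seen. The markers, gene lists, tests of each comparison, alternatives (except the neutrophil share) and the rule for naming genes were fixed before the data were examined. Some tests of explanations were chosen after the results were seen, and each is named as such.

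UMI counts were summed per library and class, since cells of 1 tumour are not replicates. Each sum was tested with edgeR 4.0.16 (R 4.3.3), using TMM factors, the default expression filter and a two-sided quasi-likelihood test, with Benjamini-Hochberg adjustment over the genes tested in that class and a threshold of 0.05. Fold changes are log2 values of Smyd3 ASO over control with standard errors (SE). Levels are edgeR's CPM values (UMI counts scaled to a common library size) from its normalised library sizes, as mean ± SD. A class entered with libraries of at least 20 cells, so B-like cells were compared with 2 control and 3 Smyd3 ASO libraries. Pericyte-like cells (77) and mast or basophil-like cells (75) were not tested. A gene at under 10% of the mean CPM of another class is described as open to free RNA, meaning RNA that leaks from other cells into droplets.

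The 34 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, with adjustment over the lists of a class. Camera with an estimated correlation and fry were run beside it. Adjusted p-values of lists come from camera unless another test is named. Shares of cells were compared by a two-sided exact permutation test over all 20 assignments of 3 libraries to each group. Its smallest possible p is 0.1, so no share could pass 0.05 by it. An edgeR test on cell counts, which can pass, was run as an alternative for the cell classes. To compare shares of cells with a UMI of a gene, each cell was thinned to a fixed number of UMIs and shallower cells were left out.

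The genes named are, for each class, up to 10 rises and 10 falls among called genes with non-overlapping groups and a mean of at least 10 CPM. In classes with fewer called genes the 5 smallest p-values are given, and from a list up to 4 members. A fixed set that always includes Smyd3 is given whatever its test. On simulated counts with 200 changed genes, the edgeR step recovered 48% of 2-fold and 88% of 4-fold changes in epithelial-like cells (14730 genes), 70% and 94% in macrophage or monocyte-like cells (11546 genes), 58% and 96% in neutrophil-like cells (9389 genes), 73% and 93% in T-like cells (10559 genes) and 61% and 92% in NK-like cells (6294 genes). False calls, on genes left unchanged, were 12 of 148 calls in epithelial-like, 19 of 183 in macrophage or monocyte-like, 6 of 160 in neutrophil-like, 15 of 181 in T-like and 9 of 162 in NK-like cells. The simulated genes varied independently, without differences shared by the genes of a library. The 200 planted changes also ease the adjusted threshold, which the few calls of the real fits do not. These rates therefore do not carry over to the real fits, where few calls do not show that few genes changed.

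The alternatives were RLE size factors, DESeq2 1.42.0, no expression filter, the replicate number as a block, each library left out, a stricter cell filter (500 genes, 10% mitochondrial UMIs), called doublets kept, Leiden resolutions 0.5 and 2, genes open to free RNA left out, and a minimum of 50 cells. The share of neutrophil-like cells as a covariate was added after the data were seen.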

Results

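Single-cell RNA was measured in 6 MOC1 tumours, a mouse model of oral cancer, after 18 days of antisense oligonucleotides (ASOs). The control ASO group and the Smyd3 ASO group held 3 tumours each, with 1 library per tumour. Between 34323332 and 54551408 UMIs were counted per library. Kept cells numbered 4077, 2747 and 5014 in control replicates 1, 2 and 3, and 3577, 3507 and 3922 in Smyd3 ASO replicates 1, 2 and 3. Their median depth ran from 4185 to 5864 UMIs per cell. The named classes held 6073 neutrophil-like, 5762 macrophage or monocyte-like, 3831 epithelial-like, 2590 T-like, 1217 fibroblast-like, 881 dendritic-like, 448 B-like, 422 erythroid-like, 408 NK-like and 307 endothelial-like cells. Values below are CPM as mean ± SD with n = 3 per group, except in B-like cells (2 control and 3 Smyd3 ASO libraries), and adjusted p-values of genes come from edgeR.

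The first question was whether Smyd3, a SET and MYND domain lysine methyltransferase and the ASO target, was lower in the treated tumours. Summed over all cells of a library, Smyd3 (ENSMUSG00000055067, GRCm38 chromosome 1, 178951960 to 179518041) stood at 241 ± 29.1 CPM in control tumours and at 95.5 ± 18.5 CPM in Smyd3 ASO tumours. By library the values were 259, 257 and 208 CPM in controls and 84.9, 117 and 84.9 CPM under the Smyd3 ASOs. The log2 fold change was −1.34 (SE 0.16), which left 39.6% of the control level. As a gene chosen before the data were examined, Smyd3 had an unadjusted p of 9.5e-05 (edgeR). Its adjusted p over 18113 genes was 0.53. Smyd3 was lower in 9 of 9 cell classes, and in 8 of them the libraries of the groups did not overlap, where chance gives 10% for 3 against 3 libraries and more for the 2 against 3 of B-like cells. The classes come from the same 6 tumours and are not independent. It fell in T-like cells from 1023 ± 85.5 to 391 ± 24.9 CPM (log2 −1.39, SE 0.11, adjusted p = 0.0041). It also fell in NK-like cells, from 1284 ± 168 to 673 ± 117 CPM (log2 −0.93, SE 0.16, adjusted p = 0.035), and in neutrophil-like cells, from 157 ± 20 to 54.6 ± 9.1 CPM (log2 −1.53, SE 0.17, adjusted p = 0.0051).

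In epithelial-like cells, the class that would hold the tumour cells, Smyd3 was 123 ± 17.6 CPM in controls and 61.0 ± 21.1 CPM under the Smyd3 ASOs. The log2 fold change was −1.02 (SE 0.25, edgeR unadjusted p = 0.0047, adjusted p = 1.0). The epithelial level was 9.91% of that in NK-like cells, so the epithelial value is open to free RNA. Neutrophil-like, macrophage or monocyte-like and dendritic-like cells, at 11.1%, 10.7% and 10.9%, lay just above the 10% limit. Their Smyd3 values are thus not clear of free RNA either. Within epithelial-like clusters the log2 fold change was −2.56 in cluster 2, where Smyd3 passed (edgeR adjusted p = 0.012), −1.11 in cluster 9 (adjusted p = 0.61) and −0.50 in cluster 19 (adjusted p = 0.96). Whether the clusters differ was not tested. After thinning each epithelial-like cell to 5000 UMIs, 35.0% ± 4.2 of control cells and 17.6% ± 5.4 of Smyd3 ASO cells held a Smyd3 UMI (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). In neutrophil-like cells thinned to 1000 UMIs the shares were 10.5% and 4.38%, and in T-like cells at that depth 47.5% and 23.2%. Macrophage or monocyte-like cells held 120 ± 8.5 and 82.7 ± 14.7 CPM (log2 −0.53, SE 0.13), and dendritic-like cells 114 ± 15.5 and 93.4 ± 17.8 CPM (log2 −0.29, SE 0.18), with overlapping groups in the latter. B-like cells held 450 ± 179 and 185 ± 1.9 CPM (log2 −1.30, SE 0.25, adjusted p = 0.11). In fibroblast-like cells (80.1 and 40.6 CPM) and endothelial-like cells (84.8 and 25.0 CPM) the values are open to free RNA. A test of whether the Smyd3 change differed between 8 classes gave an unadjusted p of 0.00045 and an adjusted p of 0.745 over 15052 genes (edgeR). Among relatives of Smyd3 in epithelial-like cells, Smyd2, Smyd4 and Smyd5 had log2 fold changes of 0.03, 0.15 and 0.05, and none passed the test.

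**Figure D1:**
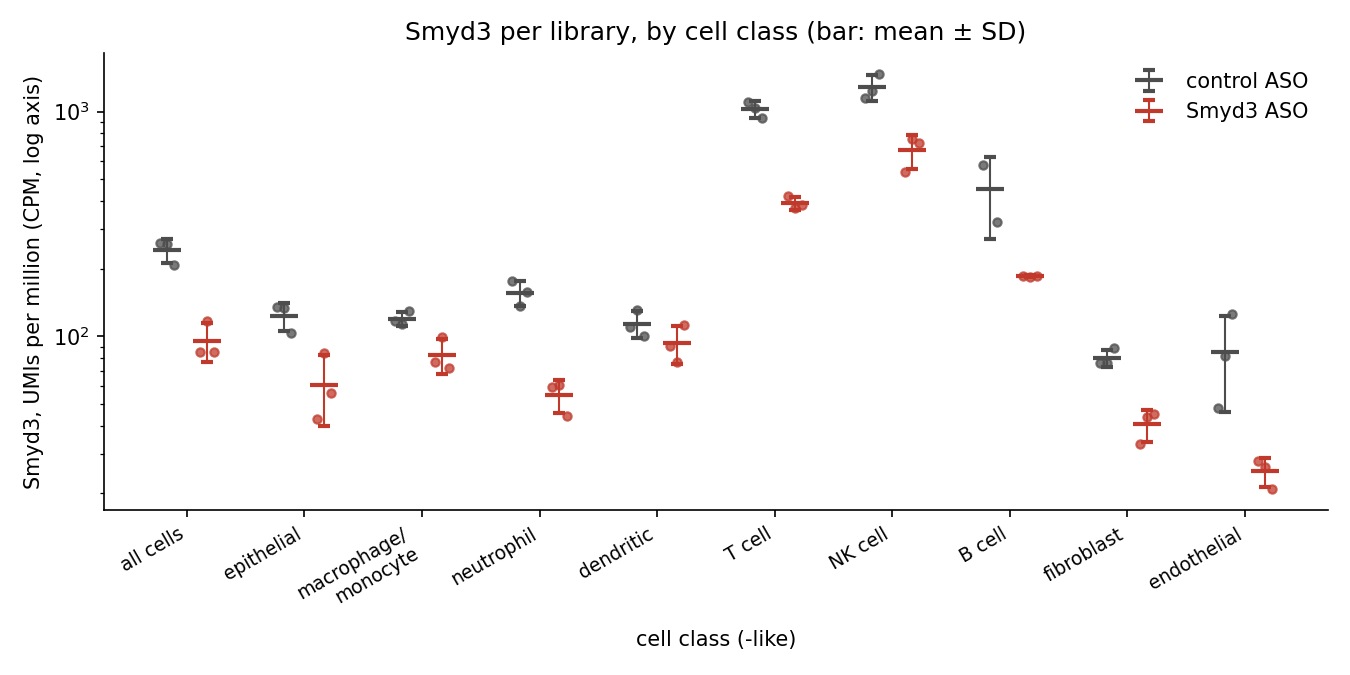
Smyd3 in CPM (log axis) for each library, over all cells and by cell class, with bars for the mean and SD of the control ASO and Smyd3 ASO groups. The groups do not overlap in 8 of the 9 classes, and T-like and NK-like cells hold the highest levels.

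The series asks how the expression profile of each cell type in the tumour differed under the Smyd3 ASOs. Fkbp5 and Ccnd3, picked after their values were seen, were higher in the Smyd3 ASO tumours in every class tested. How many other genes were higher in every class was not counted. The classes also share the same tumours, so the counts of classes describe this pair and do not test it. Fkbp5 (ENSMUSG00000024222, GRCm38 chromosome 17, 28399094 to 28517527), a co-chaperone of steroid hormone receptors that glucocorticoids induce, was higher in 9 of 9 classes, 8 of them without overlap between the groups. It rose in macrophage or monocyte-like cells from 21.9 ± 1.7 to 166 ± 50.9 CPM (log2 2.92, SE 0.23, adjusted p = 0.011). In B-like cells it rose from 22.8 ± 1.7 to 142 ± 32.4 CPM (log2 2.64, SE 0.30, adjusted p = 0.017). In neutrophil-like cells it rose from 37.6 ± 8.7 to 122 ± 15.7 CPM (log2 1.73, SE 0.19, adjusted p = 0.0051), and in NK-like cells from 100.6 ± 3.9 to 209 ± 13.1 CPM (log2 1.05, SE 0.17, adjusted p = 0.029). Fkbp5 did not pass the test in dendritic-like cells (40.7 and 145 CPM, adjusted p = 0.21), T-like cells (98.2 and 208 CPM, adjusted p = 0.082) or fibroblast-like cells (49.6 and 129 CPM, adjusted p = 0.73).

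Ccnd3 (ENSMUSG00000034165, GRCm38 chromosome 17, 47505051 to 47599691), which encodes cyclin D3, a driver of the G1 to S step of the cell cycle, was also higher in 9 of 9 classes, 7 of them without overlap. In epithelial-like, fibroblast-like and endothelial-like cells its level was 5.10%, 6.94% and 5.28% of that in NK-like cells, so these 3 values are open to free RNA. It rose in neutrophil-like cells from 346 ± 40.6 to 1114 ± 183 CPM (log2 1.69, SE 0.17, adjusted p = 0.0050) and in NK-like cells from 875 ± 8.1 to 1569 ± 131 CPM (log2 0.84, SE 0.14, adjusted p = 0.029). Values that did not pass were 150 and 414 CPM in macrophage or monocyte-like cells (adjusted p = 0.28) and 553 and 997 CPM in T-like cells (adjusted p = 0.057). Epithelial-like cells showed the smallest difference for both genes, with log2 fold changes of 0.35 for Fkbp5 and 0.23 for Ccnd3. The size of the change differed between 8 classes for Fkbp5 (interaction adjusted p = 5.3e-06, edgeR) and for Ccnd3 (interaction adjusted p = 0.0445, edgeR). Tsc22d3, another glucocorticoid-induced gene chosen after these values were seen, was higher in 9 of 9 classes, with 1 class free of overlap and none past the test.

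**Figure D2:**
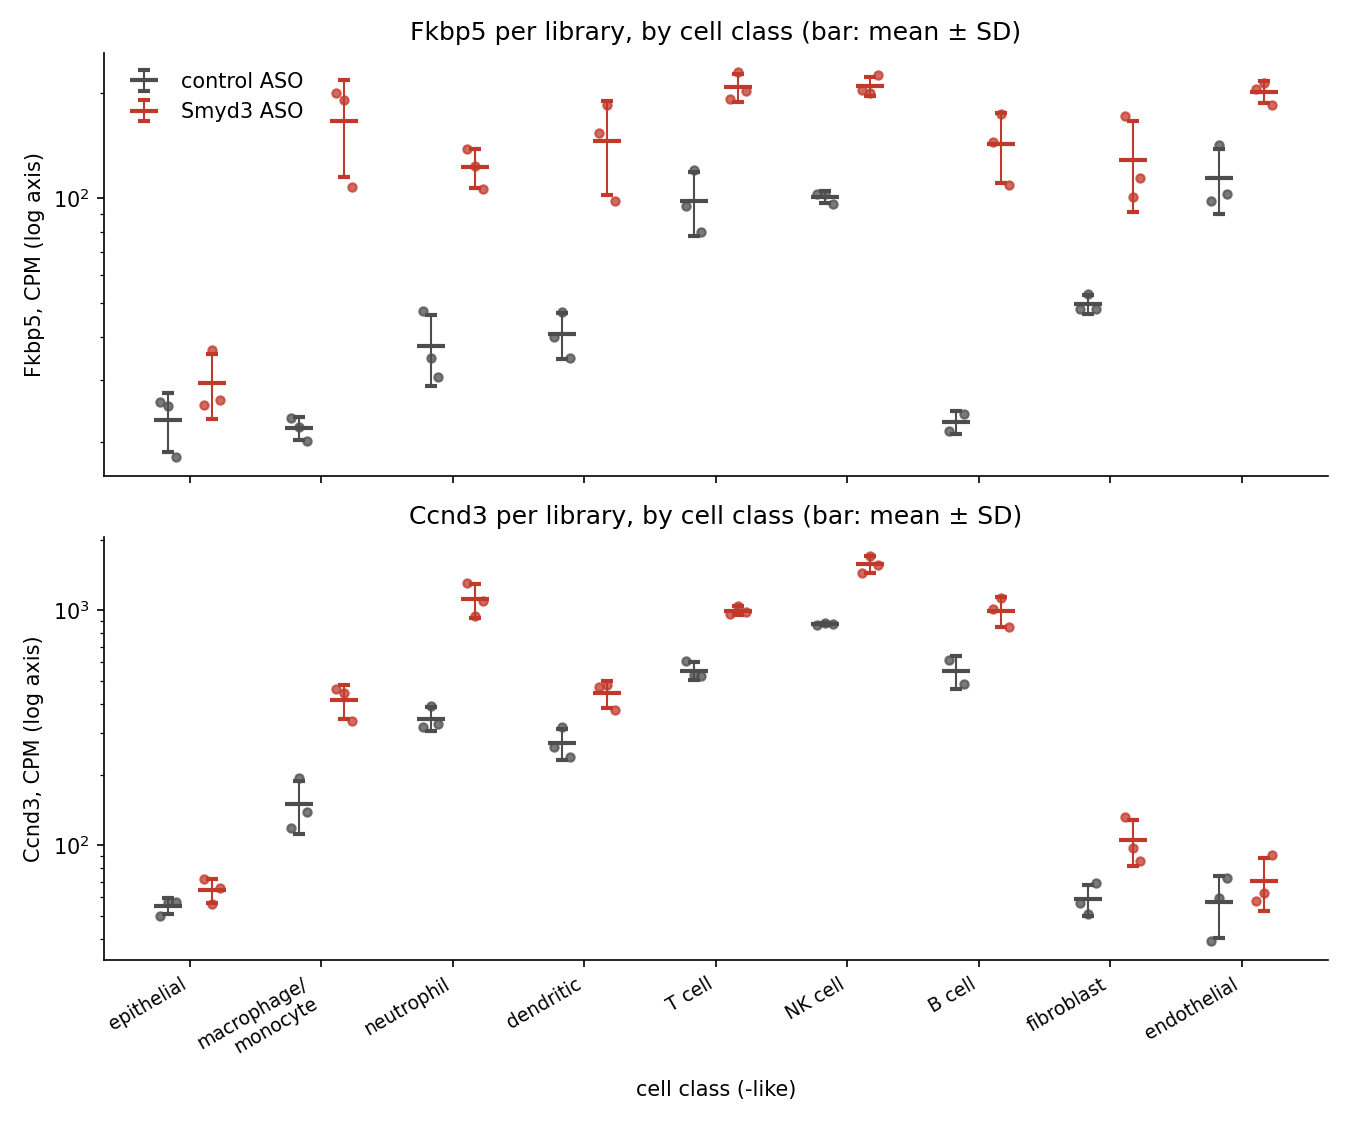
Fkbp5 (top) and Ccnd3 (bottom) in CPM on log axes for each library of each cell class, with bars for the mean and SD of each group. Fkbp5 reaches 166 CPM in macrophage or monocyte-like cells from 21.9 CPM in controls, and Ccnd3 reaches 1114 CPM in neutrophil-like cells from 346 CPM.

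In epithelial-like cells, genes of interferon signalling and antigen presentation stood higher in the Smyd3 ASO tumours, and genes of hypoxia and glycolysis stood lower. The type I interferon response list was higher for 37 of 38 members, with a median log2 fold change of 0.39 (camera adjusted p = 1.0e-16, adjusted p = 0.53 with an estimated correlation). The interferon gamma response list was higher for 32 of 32 members, with a median of 0.35 (camera adjusted p = 2.9e-19, adjusted p = 0.46 with an estimated correlation). All 23 members of MHC class I presentation were higher, with a median of 0.22 (camera adjusted p = 1.1e-07, adjusted p = 0.53 with an estimated correlation). The chemokines that attract T cells had a median of 0.59 over 8 members (camera adjusted p = 2.2e-07, adjusted p = 0.30 with an estimated correlation), with 4 members open to free RNA and a median of 0.31 with called doublets kept. Cxcl10 (ENSMUSG00000034855), a CXCR3 ligand, stood at 52.0 ± 8.2 CPM in controls and 112 ± 12.6 CPM under the Smyd3 ASOs (log2 1.11, SE 0.15, adjusted p = 0.86). Its relative Cxcl9 stood at 150 and 213 CPM. Other members with small p-values were Dhx58, an RNA sensor relative (log2 0.60), Nlrc5, the transactivator of MHC class I genes (log2 0.46), Psmb10, an immunoproteasome subunit (log2 0.43), and the peptidase inhibitor Serpina3g (log2 0.71). For genes of antigen presentation given in every case, the log2 fold change was 0.04 for B2m, 0.10 for H2-K1, 0.06 for H2-D1, 0.26 for Tap1 and 0.48 for Cd274.

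The count "adjusted over the list alone" was 0 of 38 for type I interferon, 1 of 32 for interferon gamma (Cxcl10), 0 of 23 for MHC class I and 2 of 8 for the T cell chemokines (Cxcl10 and Cxcl9). Smyd3 ASO replicate 1 weighed on these lists, since without it the medians were 0.11 for type I interferon, 0.12 for interferon gamma and 0.10 for MHC class I, and without control replicate 2 that of interferon gamma was 0.20. The type I interferon list also differed along another division of the libraries, with a median of 0.48 for control replicate 3 and Smyd3 ASO replicates 1 and 3 over the other 3. That division follows the share of neutrophil-like cells, which was 36.6%, 32.2% and 36.0% in the former and 14.3%, 20.3% and 15.2% in control replicates 1 and 2 and Smyd3 ASO replicate 2. With the neutrophil share as a covariate, chosen after the data were seen, the medians were 0.31 for type I interferon, 0.33 for interferon gamma and 0.22 for MHC class I. Within clusters 2, 9, 10 and 19 of the epithelial-like cells the type I interferon median was 0.34, 0.53, 0.74 and 0.91.

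Hypoxia and glycolysis genes fell as a list in epithelial-like cells, with 31 of 34 members lower and a median of −0.28 (camera adjusted p = 1.5e-21, adjusted p = 0.21 with an estimated correlation). Adjusted over the list alone, 9 members passed, and none passed over all genes. Ddit4, a stress-induced inhibitor of mTORC1, was 52.1 and 33.1 CPM (log2 −0.66). Pdk1, a pyruvate dehydrogenase kinase, was 44.8 and 30.4 CPM (log2 −0.56) and Ndrg1 298 and 172 CPM (log2 −0.80). The histone demethylase Kdm3a was 86.0 and 63.9 CPM (log2 −0.43). Oxidative phosphorylation genes rose as a list by a small amount, with 29 of 31 members higher and a median of 0.11 (camera adjusted p = 4.4e-05, adjusted p = 0.53 with an estimated correlation, median 0.18 without control replicate 3). Myeloid attracting chemokines and growth factors had 12 of 14 members higher and a median of 0.28 (camera adjusted p = 0.00021, adjusted p = 0.21 with an estimated correlation). Among them Il34, a ligand of the CSF1 receptor, had a log2 fold change of 0.50 and passed the test adjusted over the list alone. This median ranged from 0.16 without control replicate 2 to 0.52 without control replicate 3, and was 0.50 with genes open to free RNA left out. Erythrocyte genes were lower by a median of −3.00 (camera adjusted p = 4.9e-05, adjusted p = 0.53 with an estimated correlation), which became −0.39 without control replicate 1, the library with 8.09% erythroid-like cells. Of 33 lists tested in epithelial-like cells 16 were called, 14 up and 2 down. Over 14925 genes edgeR called 0 at an adjusted p under 0.05, with 472 at an unadjusted p under 0.05, and DESeq2 called 15.

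**Figure D3:**
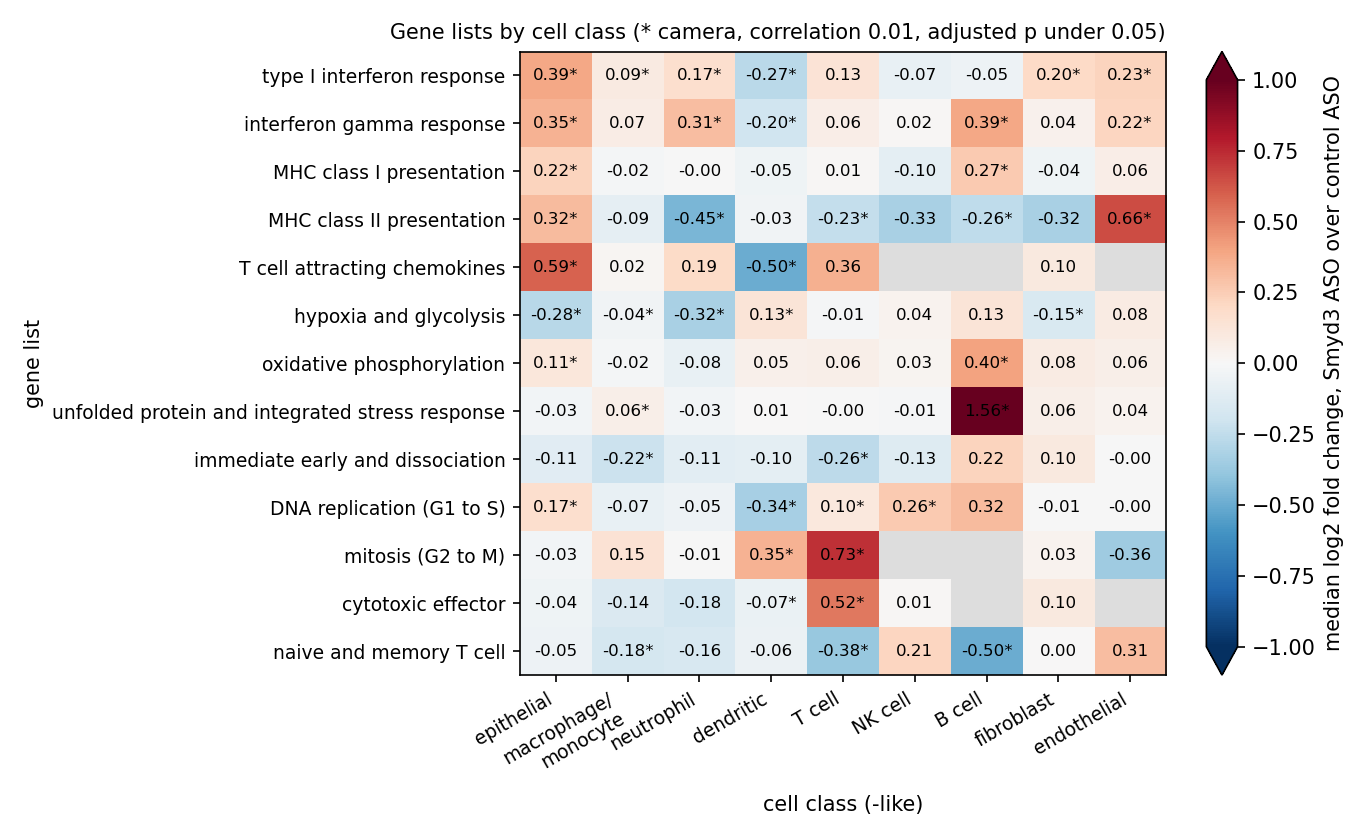
Median log2 fold change (Smyd3 ASO over control ASO, colour scale) of 13 gene lists in 9 cell classes, with asterisks for a camera adjusted p under 0.05 at a preset correlation of 0.01 and grey for lists not tested. Interferon lists have positive medians in epithelial-like cells (0.39 and 0.35) and negative ones in dendritic-like cells (−0.27 and −0.20).

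In neutrophil-like cells the hypoxia and glycolysis list was lower and the interferon gamma list higher in the Smyd3 ASO tumours. Neither list was tested within the neutrophil-like clusters, whose shares varied between libraries. Cluster 8 held 24.5% of neutrophil-like cells in controls and 14.9% under the Smyd3 ASOs (two-sided exact permutation p = 0.4), so a shift between clusters stays open. For hypoxia and glycolysis 29 of 32 members were lower, with a median of −0.32 (camera adjusted p = 3.6e-13, adjusted p = 0.39 with an estimated correlation), and 6 passed adjusted over the list alone. Ero1l, an oxidase of the endoplasmic reticulum, was 727 and 465 CPM, and Egln3, an oxygen-sensing prolyl hydroxylase, was 665 and 450 CPM, while Bnip3, a mitophagy receptor, had a log2 fold change of −0.51. The interferon gamma list was higher for 25 of 28 members, with a median of 0.31 (camera adjusted p = 3.4e-07, adjusted p = 0.50 with an estimated correlation, 0 adjusted over the list alone). It included the interferon-inducible GTPase genes Gbp5 (log2 0.64), Irgm2 (log2 0.54), Igtp (log2 0.43) and Gbp2 (log2 0.44). The type I interferon list had a median of 0.17 (camera adjusted p = 0.00029, adjusted p = 0.93 with an estimated correlation). That median was 0.11 without control replicate 1, 0.27 without control replicate 2 and 0.27 without Smyd3 ASO replicate 2. The call ended without control replicate 3 (0.13, adjusted p = 0.053) and without Smyd3 ASO replicate 1 (−0.03, adjusted p = 0.71). edgeR called 3 of 9617 genes, which were Ccnd3, Fkbp5 and Smyd3. Without Smyd3 ASO replicate 1 none of the 3 passed (adjusted p = 0.055), and Smyd3 did not pass without Smyd3 ASO replicate 3 (adjusted p = 0.077). The count was 5 without control replicate 1, 11 without control replicate 3 and 2 without Smyd3 ASO replicate 3. Sla, an adaptor that dampens receptor signalling, stood at 113 ± 11.6 and 213 ± 6.3 CPM (log2 0.91, adjusted p = 0.072).

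Macrophage or monocyte-like cells had Fkbp5 as the only called gene among 11712 tested with edgeR. Its call was lost without any of control replicates 1, 2 and 3 (adjusted p = 0.13, 0.075 and 0.14). Mertk, a receptor for the uptake of dying cells, stood at 178 ± 17.3 and 279 ± 32.8 CPM (log2 0.65, adjusted p = 1.0), and Nos2, the inducible nitric oxide synthase, at 14.5 and 6.99 CPM (log2 −1.06). Genes given in every case showed log2 fold changes of 0.05 for Arg1, 0.45 for Mrc1, 0.03 for Spp1, 0.07 for Cxcl9, 0.01 for Cxcl10, −0.07 for H2-Ab1 and −0.10 for Cd274, and none passed the test. The list of immediate early and dissociation genes fell, with 21 of 27 members lower and a median of −0.22 (camera adjusted p = 3.2e-05, adjusted p = 0.70 with an estimated correlation, 0 adjusted over the list alone). Its transcription factor genes Atf3 and Maff had log2 fold changes of −0.33 and −0.35, and the chaperone gene Dnajb1 one of 0.42. Without control replicate 2 the list no longer passed (median −0.13, adjusted p = 0.082). Of 30 lists 7 were called, 2 up and 5 down.

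In dendritic-like cells the interferon lists were lower in the Smyd3 ASO tumours, with calls that rested on control replicate 3. Of 35 type I interferon members 33 were lower, with a median of −0.27 (camera adjusted p = 4.6e-08, adjusted p = 0.59 with an estimated correlation, 0 adjusted over the list alone), and 11 members are open to free RNA. Of 25 interferon gamma members 24 were lower, with a median of −0.20 (camera adjusted p = 7.9e-06, adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone 1 passed, Iigp1, an interferon-inducible GTPase that is open to free RNA. All 8 chemokines that attract T cells were lower, with a median of −0.50 (camera adjusted p = 0.0064, adjusted p = 0.59 with an estimated correlation, 0 adjusted over the list alone). The difference between the changes in epithelial-like and dendritic-like cells was 0.614 for interferon gamma (two-sided exact permutation p = 0.1) and 0.676 for type I interferon (exact permutation p = 0.2, overlapping groups). Without control replicate 3 the medians were −0.07 for type I interferon (adjusted p = 0.27), −0.02 for interferon gamma (adjusted p = 0.16) and −0.13 for the chemokines (adjusted p = 0.58). The type I interferon median was −0.43 without control replicate 1 and −0.42 without Smyd3 ASO replicate 2, and that of interferon gamma −0.32 without Smyd3 ASO replicate 3. For the chemokines it was −0.29 without control replicate 1, −0.29 without Smyd3 ASO replicate 1 (adjusted p = 0.24), −0.36 without Smyd3 ASO replicate 2 (adjusted p = 0.057) and −0.90 without Smyd3 ASO replicate 3. With genes open to free RNA left out the chemokine median was −0.29 (adjusted p = 0.081). Of 30 lists 12 were called, 4 up and 8 down. Among genes, edgeR called 0 of 9756, with 233 at an unadjusted p under 0.05, and DESeq2 called 1. edgeR called 1 gene without Smyd3 ASO replicate 3.

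T-like cells carried more mitotic and cytotoxic transcripts and fewer transcripts of the naive and memory state in the Smyd3 ASO tumours. Of 30 mitosis genes 29 were higher, with a median of 0.73 (camera adjusted p = 3.9e-26, adjusted p = 0.45 with an estimated correlation), and 17 passed adjusted over the list alone. Examples were Kif11, a spindle motor (34.4 and 63.1 CPM), Anln, a scaffold of cell division (10.6 and 21.4 CPM), and Tpx2, a spindle assembly factor (log2 0.76). Cluster 35, a T-like cluster with cell cycle genes in the lead, held 2.64% of control and 3.87% of Smyd3 ASO T-like cells (two-sided exact permutation p = 0.1). Cytotoxic effector genes were higher for 16 of 21 members, with a median of 0.52 (camera adjusted p = 9.0e-05, adjusted p = 0.51 with an estimated correlation, 0 adjusted over the list alone). They included the receptor Klrd1 (log2 0.57), the protease inhibitor Cst7 (log2 0.43) and the chemokine Ccl4 (log2 0.65), and the call ended without Smyd3 ASO replicate 1 (median 0.15, adjusted p = 0.21). In that library the CD8 subset was 43.9% of T-like cells, against 29.3% and 21.2% in the other Smyd3 ASO libraries and 29.9%, 18.1% and 19.4% in the controls. Gzmb, Prf1 and Ifng had log2 fold changes of 0.76, 0.64 and 0.71, Cd8a 0.34, Foxp3 0.00 and Tcf7 −0.35, and none passed the test.

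Exhaustion genes of T-like cells were higher for 16 of 20 members, with a median of 0.14 (camera adjusted p = 0.00013, adjusted p = 0.51 with an estimated correlation). Pdcd1, which encodes the PD-1 receptor, stood at 147 and 235 CPM (log2 0.68, adjusted p = 0.20) and was the 1 member to pass adjusted over the list alone. The receptors Tigit and Havcr2 had log2 fold changes of 0.44 and 0.60. The exhaustion call ended without control replicate 3 (median 0.12, adjusted p = 0.14), while the median was 0.26 without control replicate 2 and 0.06 at Leiden resolution 2. Naive and memory genes were lower for 14 of 16 members, with a median of −0.38 (camera adjusted p = 2.6e-07, adjusted p = 0.51 with an estimated correlation), and 1 member, Igfbp4 (log2 −1.13), passed adjusted over the list alone. S1pr1, the receptor for egress from lymphoid tissue, and Klf2, a factor of quiescence, had log2 fold changes of −0.57 and −0.41. T-like clusters 48 and 49, led by naive genes such as Lef1 and Tcf7, held 10.3% and 8.74% of T-like cells in control replicate 1 and at most 2.59% and 1.94% in any other library. Control replicate 1 also weighed on this list, with a median of −0.12 without it, and at Leiden resolution 2 the list no longer passed (median −0.04, adjusted p = 0.40). Immediate early genes fell as a list, with 19 of 27 members lower and a median of −0.26 (camera adjusted p = 1.3e-06, adjusted p = 0.43 with an estimated correlation, 0 adjusted over the list alone). Fos, Fosb and Ier2, which respond within minutes to stimulation, had log2 fold changes of −0.51, −0.46 and −0.39, and the median was −0.16 without control replicate 2.

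The called genes of T-like cells, 3 of 10697 with edgeR, were Smyd3, Nrn1 and Dthd1. Nrn1 (ENSMUSG00000039114, GRCm38 chromosome 13, 36725361 to 36735131), which encodes neuritin, rose from 18.0 ± 2.7 to 53 ± 1.7 CPM (log2 1.56, SE 0.15, adjusted p = 0.0042). Dthd1 (ENSMUSG00000090326), a death domain gene at a level under the naming rule and named after its values were seen, rose from 1.79 ± 0.42 to 15.8 ± 0.50 CPM (log2 3.13, SE 0.28, adjusted p = 0.0042). Without Smyd3 ASO replicate 2 none of the 3 passed (adjusted p = 0.053). The count was 5 without control replicate 1, 9 without control replicate 2 and 4 without control replicate 3. Of 31 lists 12 were called in T-like cells, 6 up and 6 down.

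In NK-like cells edgeR called 5 of 6482 genes, among them Fkbp5, Ccnd3 and Smyd3. Angpt1 (ENSMUSG00000022309), which encodes the vessel growth factor angiopoietin-1, rose from 33.8 ± 6.6 to 104 ± 25.5 CPM (log2 1.58, SE 0.27, adjusted p = 0.029). Sema6a (ENSMUSG00000019647), a transmembrane semaphorin, rose from 47.5 ± 8.5 to 123 ± 24.6 CPM (log2 1.34, SE 0.24, adjusted p = 0.035). The number of these 5 genes still called was 0 without control replicate 1, control replicate 2, Smyd3 ASO replicate 1 or Smyd3 ASO replicate 3, 4 without control replicate 3 (which called 10) and 3 without Smyd3 ASO replicate 2. Without control replicate 2 edgeR called 1 other gene. Of 22 lists 4 were called, 2 up and 2 down.

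B-like cells of the Smyd3 ASO tumours carried more transcripts for secretory protein folding than those of control replicates 1 and 3, the controls that entered. The list of unfolded protein and integrated stress response genes was higher for 16 of 16 members, with a median of 1.56 (camera adjusted p = 8.5e-25, adjusted p = 0.27 with an estimated correlation), and 14 passed adjusted over the list alone. Creld2 (ENSMUSG00000023272), an endoplasmic reticulum chaperone, rose from 14.3 ± 13.7 to 149 ± 48.4 CPM (log2 3.66, adjusted p = 0.046). Herpud1 (ENSMUSG00000031770), a factor of endoplasmic reticulum degradation, rose from 79.8 ± 20.1 to 349 ± 122 CPM (log2 2.16, adjusted p = 0.048). Other rises were in Rpn1, an oligosaccharyltransferase subunit (60.4 to 213 CPM, adjusted p = 0.045), Creb3l2, a transcription factor of the secretory pathway (23.9 to 124 CPM, adjusted p = 0.046), and Fndc3b (32.9 to 167 CPM, adjusted p = 0.046). The naive and memory list, which includes Ccr7 (log2 −1.04) and Bach2 (log2 −0.85), was lower for 8 of 8 members with a median of −0.50 (camera adjusted p = 0.00062, adjusted p = 0.27 with an estimated correlation), and 2 passed adjusted over the list alone. A plasma-like cluster led by Ighg1, Igkc, Jchain and Mzb1 held 1.56% and 6.56% of B-like cells in control replicates 1 and 3, and 12.7%, 18.6% and 17.2% in Smyd3 ASO replicates 1, 2 and 3. It held 23.5% in control replicate 2, which had too few B-like cells to enter the test. Over all 6 libraries this cluster was 10.5% of control and 16.2% of Smyd3 ASO B-like cells (two-sided exact permutation p = 0.5). The genes and lists were not tested within the B-like clusters, so a shift between clusters stays open. The 6 genes rested on 2 control libraries, so each fit without a control has 1 control library, which is assumed to vary like the Smyd3 ASO libraries: 0 of them were called without control replicate 1, 6 (of 199 called) without control replicate 3, 5 without Smyd3 ASO replicate 1, 1 without Smyd3 ASO replicate 2 and 1 without Smyd3 ASO replicate 3. Without control replicate 1 the medians were 0.84 for the unfolded protein list and −0.27 for the naive list, and with called doublets kept the former was 0.71.

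Among stromal cells, Zbtb16 (ENSMUSG00000066687), a zinc finger transcription factor, stood at 18.9 ± 6.9 and 182 ± 55.1 CPM in fibroblast-like cells (log2 3.26, SE 0.33, adjusted p = 0.15). In endothelial-like cells it stood at 4.97 ± 0.86 and 102 ± 92.7 CPM (log2 4.24, SE 0.77, adjusted p = 0.88). The difference was not confined to stromal cells, as Zbtb16 was higher in 6 of 7 classes tested, 4 of them without overlap. It passed in none, and was lower in T-like cells. In macrophage or monocyte-like cells it stood at 14.4 ± 3.4 and 33.2 ± 12.3 CPM, and its neutrophil-like and dendritic-like values are open to free RNA. The protocadherin gene Pcdh9 stood at 93.5 ± 20.4 and 36.3 ± 4.2 CPM in fibroblast-like cells (log2 −1.36, adjusted p = 0.66). Type I interferon genes were higher in fibroblast-like cells for 30 of 36 members, 14 of them open to free RNA, with a median of 0.20 (camera adjusted p = 1.9e-05, adjusted p = 0.95 with an estimated correlation, 0 adjusted over the list alone, median 0.35 without control replicate 3). No gene passed in fibroblast-like cells (edgeR 0 of 11786, 369 at an unadjusted p under 0.05, DESeq2 11) or in endothelial-like cells (edgeR 0 of 7802, 208 at an unadjusted p under 0.05, DESeq2 3). Of the lists, 4 of 30 were called in fibroblast-like cells and 5 of 25 in endothelial-like cells.

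Summed over all cells, MHC class II genes were lower and basal keratinocyte genes higher in the Smyd3 ASO tumours. These sums move with the make-up of the tumours, in which epithelial-like cells were 14.6% of control and 19.2% of Smyd3 ASO cells, and dendritic-like cells 4.58% and 3.36%. Within dendritic-like and macrophage or monocyte-like cells the MHC class II list had medians of −0.03 and −0.09 and did not pass (camera adjusted p = 0.72 and 0.50). All 12 MHC class II members were lower, with a median of −0.50 (camera adjusted p = 2.2e-11, adjusted p = 0.25 with an estimated correlation), and 9 passed adjusted over the list alone. They included Ciita, the transactivator of MHC class II genes (log2 −0.54), and the class II chain gene H2-Aa (log2 −0.50). All 16 basal keratinocyte members were higher, with a median of 0.37 (camera adjusted p = 1.8e-08, adjusted p = 0.41 with an estimated correlation, 2 adjusted over the list alone, median 0.18 without control replicate 3). Erythrocyte genes had a median of −3.81 (camera adjusted p = 1.2e-06, adjusted p = 0.41 with an estimated correlation, 5 of 5 adjusted over the list alone), or −1.90 without control replicate 1. The SMYD family list was called down although its median of 0.04 was above 0, with a mean of −0.28. Of 33 lists 23 were called, 10 up and 13 down, while edgeR called 0 of 18113 genes, with 1449 at an unadjusted p under 0.05, and DESeq2 called 156. Over every class and all cells 99 of 284 list tests were called with camera at the preset correlation, 54 up and 45 down. With an estimated correlation 0 were (adjusted p from 0.16 to 0.95), and with fry 1 was, the SMYD family in T-like cells (adjusted p = 0.014).

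The last question was whether the make-up of the tumours differed. Epithelial-like cells were 14.6% ± 1.9 of control cells and 19.2% ± 1.3 of Smyd3 ASO cells (two-sided exact permutation p = 0.1, the smallest possible, BH-adjusted 0.6), with no overlap between the groups. Erythroid-like cells were 3.30% ± 4.16 and 0.265% ± 0.262 (exact permutation p = 0.1, BH-adjusted 0.6). As a percentage of non-epithelial cells they were 3.93% and 0.331%, with overlapping groups (exact permutation p = 0.2). Control replicate 1 held 8.09%, against 1.20% and 0.598% in the other control libraries. The groups overlapped for neutrophil-like cells (23.8% ± 11.5 and 27.8% ± 11.1), macrophage or monocyte-like cells (26.7% ± 3.7 and 24.6% ± 6.7), T-like cells (12.7% ± 3.2 and 10.3% ± 2.6) and fibroblast-like cells (4.65% ± 0.90 and 6.00% ± 1.85). They also overlapped for dendritic-like cells (4.58% ± 1.45 and 3.36% ± 0.93). Among T-like cells the CD8 subset was 22.4% ± 6.5 in controls and 31.5% ± 11.5 under the Smyd3 ASOs (exact permutation p = 0.3), a difference of 2.80 percentage points without Smyd3 ASO replicate 1. Regulatory T cells were 22.1% ± 6.5 and 22% ± 3.3, and gamma-delta T cells 4.65% ± 3.48 and 1.51% ± 1.08 (exact permutation p = 0.2). Unnamed sub-clusters held 34.6% ± 4.9 of T-like cells in controls and 29.8% ± 4.5 under the Smyd3 ASOs. The largest CD8 sub-cluster (318 cells) was led by Gzma and had no CD8 marker among its top 10 genes, although 8 were raised. After thinning to 2000 UMIs, 23.9% of control and 31.0% of Smyd3 ASO T-like cells held a Cd8a UMI, against 0.0998% and 0.247% of neutrophil-like cells. Foxp3 UMIs were found in 13.4% and 11.9% of T-like cells. Median depths before thinning were 6308 and 6076 UMIs in T-like cells and 3321 and 2980 UMIs in neutrophil-like cells.

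**Figure D4:**
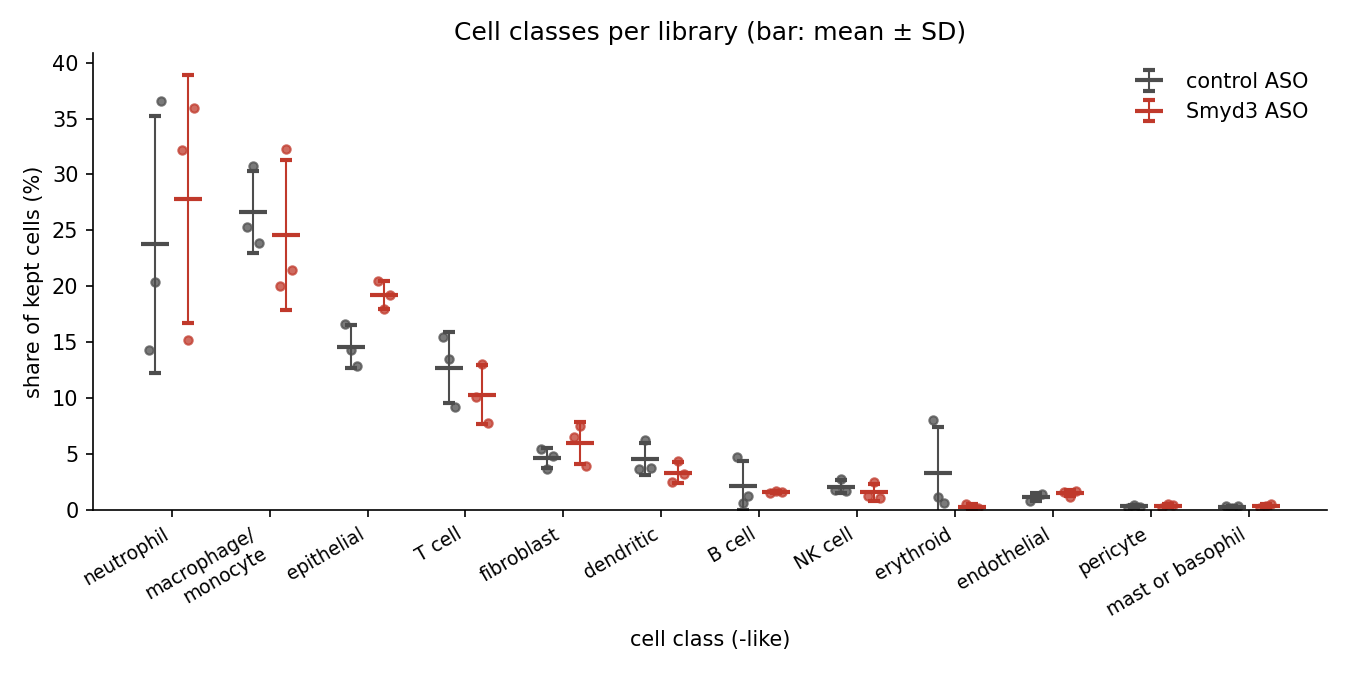
Share of kept cells (%) in each cell class for each library, with bars for the mean and SD of the control ASO and Smyd3 ASO groups. Epithelial-like cells lie higher in all 3 Smyd3 ASO libraries (19.2% on average) than in the controls (14.6%), while neutrophil-like cells spread widely within both groups.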

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

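Tests chosen only after the results were seen are the bound on Fkbp5 in T-like, NK-like and endothelial-like cells and the counts over other divisions of the libraries.

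The change between the groups differed between 8 cell classes for 4 of 15052 genes tested with an edgeR interaction term, and these were Fkbp5, Mcpt2, Zbtb16 and Ccnd3. For Fkbp5 (interaction adjusted p = 5.32e-06) the log2 fold change ran from 0.35 in epithelial-like cells to 2.92 in macrophage or monocyte-like cells. For Ccnd3 (interaction adjusted p = 0.0445) it ran from 0.23 in epithelial-like cells to 1.69 in neutrophil-like cells. Mcpt2, a mast cell protease gene, was 77.0 ± 49.2 CPM in T-like cells of controls and 6.13 ± 3.57 CPM under the Smyd3 ASOs, against 6.32 and 12.2 CPM in neutrophil-like cells (interaction adjusted p = 0.000779). An unnamed T sub-cluster led by Il13 with the mast cell protease genes Mcpt1, Mcpt2 and Mcpt8 lies in this class, with 16, 38 and 11 cells in control replicates 1, 2 and 3 and 15, 41 and 21 in Smyd3 ASO replicates 1, 2 and 3. Zbtb16 had log2 fold changes of −1.33 in T-like cells, 3.26 in fibroblast-like cells and 4.24 in endothelial-like cells (interaction adjusted p = 0.00569). In T-like cells Zbtb16 is among the leading genes of a gamma-delta sub-cluster, and gamma-delta cells were 3.18%, 8.63% and 2.16% of T-like cells in the controls and 0.276%, 1.97% and 2.29% under the Smyd3 ASOs.

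Free RNA from macrophage or monocyte-like cells was bounded by the 95th percentile of the leak of 30 macrophage markers. It stays open for Fkbp5 as a whole, since 4 of 7 classes exceeded the bound. The bound is loose in neutrophil-like and dendritic-like cells, where that percentile was 70.4% and 79.5% against a median leak of 3.45% and 11.8%. Rises of 84.3 and 102 CPM under the bound there therefore decide little. Free RNA is argued against in T-like, NK-like and endothelial-like cells, where the lowest rise was 2.40 times the bound. But these 3 classes were picked after seeing which exceeded the bound, and fibroblast-like cells (1.42 times) were within the spread. For a segment of chromosome 17 that differs between the mice, the share of genes with p under 0.05 between Fkbp5 and Ccnd3 was taken. It was 1.11 times that on other chromosomes in neutrophil-like cells and 0.97 times in macrophage or monocyte-like cells, the classes examined. This argues against a segment that changes many of its genes there. A segment that changes few genes would not move this share, so it stays open. A response to glucocorticoids, such as handling stress, may contribute. The median change of 8 to 13 other induced genes was above 0 in 7 of 8 classes. It was 0.01 in neutrophil-like cells and 0.04 in NK-like cells, where 4 of 8 members were higher. The mean of the medians, 0.142 (SD 0.188), lay under the 0.2 set beforehand for this cause. These genes did not include Tsc22d3, which was higher in 9 of 9 classes with none past the test, so the shortfall decides little. An effect of the Smyd3 ASOs, through the loss of Smyd3 or apart from it, stays open and was not tested.

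With 10 divisions of the 6 libraries, the real one included, a share under 0.05 cannot be reached. The real grouping called 0 genes in all cells and in epithelial-like, dendritic-like, fibroblast-like and endothelial-like cells, so the tally of 10 divisions with as many genes was fixed there and tests nothing. The highest other counts in these were 16, 197, 1, 6 and 3 genes. As many genes as in the real grouping were called in 2 divisions for macrophage or monocyte-like (real 1, highest other 21), 2 for neutrophil-like (real 3, highest other 32), 1 for T-like (real 3, highest other 2) and 2 for NK-like cells (real 5, highest other 39). In B-like cells, with 5 libraries, the real count was 6 and the highest other 1. For called lists in epithelial-like cells 3 divisions gave as many (real 16, highest other 17). The highest other division also called more lists than the real one in macrophage or monocyte-like (15 against 7), neutrophil-like (16 against 6), T-like (14 against 12), NK-like (7 against 4), fibroblast-like (11 against 4) and endothelial-like cells (9 against 5). It called fewer in all cells (17 against 23), dendritic-like (11 against 12) and B-like cells (7 against 10).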

How the results depend on the processing

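Added after the data were seen: the neutrophil share as a covariate. Over the alternatives, Smyd3 in all cells and in epithelial-like cells kept its direction and an unadjusted p under 0.05 in 29 of 30 fits. Its adjusted p passed in all cells with DESeq2 (8.6e-09) and with the covariate (0.046), and ran up to 1.0 in the others. Where Smyd3 was called, the call was lost in neutrophil-like cells without Smyd3 ASO replicate 1 or 3, in T-like cells without Smyd3 ASO replicate 2, and in NK-like cells without control replicate 1, control replicate 2, Smyd3 ASO replicate 1 or Smyd3 ASO replicate 3, or with called doublets kept. Counts of called genes stayed within 1.5 times in 114 of 163 fits. Many of these fits called no gene, as did the main fit, which passes by construction and tests nothing. Called lists kept direction and call in 1264 of 1690 fits, lost the call in 413 and reversed in 13, and shares of cells kept their direction in 156 of 170. Named genes kept both in 772 of 903 fits, lost the call in 71, gained it in 15 and reversed in 45. Many named genes were not called in the main fit and had no call to lose. The 772 therefore do not measure how well calls held. Unless an alternative's own construction shows it, as with fewer libraries, the cause was not tested. The Leiden resolutions gave identical values in epithelial-like cells and so test nothing there. Cell numbers limited B-like cells, where control replicate 2 had too few to enter, and pericyte-like and mast or basophil-like cells (77 and 75), which were not tested. The share of epithelial-like cells with a Smyd3 UMI, thinned to 1 depth, differed by −17.3 percentage points, where the exact test cannot pass.

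Counts of called genes with DESeq2 were 156 in all cells and 15 in epithelial-like cells (edgeR 0 in both), 3 in macrophage or monocyte-like (edgeR 1), 5 in neutrophil-like (edgeR 3), 1 in dendritic-like (edgeR 0), 19 in T-like (edgeR 3), 38 in B-like (edgeR 6), 11 in fibroblast-like and 3 in endothelial-like cells (edgeR 0 in both). With no filter they were 39 in macrophage or monocyte-like, 71 in neutrophil-like, 65 in dendritic-like, 230 in T-like, 19 in NK-like, 243 in B-like, 3 in fibroblast-like and 78 in endothelial-like cells. With the replicate block they were 5 in neutrophil-like, 1 in dendritic-like, 20 in T-like, 8 in NK-like and 115 in B-like cells. With the neutrophil share as a covariate they were 1 in all cells and 8 in NK-like cells. In NK-like cells 2 genes were called with called doublets kept and 3 at Leiden resolution 2. In B-like cells 2 were called with RLE size factors, 1 with the stricter cell filter and 1 with called doublets kept. Called lists numbered 0 with an estimated correlation and 1 with fry over the 9 classes, and 0 with either in all cells.

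Among shares of cells, the difference for mast or basophil-like cells was −0.0526 with called doublets kept, for pericyte-like cells −0.0838 at Leiden resolution 0.5, and for T cells with a Cd4 UMI, thinned to 1 depth, 0.575 against −0.982 for the other CD4 subset. Foxp3 in T-like cells (0.00) was −0.0011 with RLE size factors and −0.0011 with DESeq2, −0.022 with no filter, −0.059 with the covariate, −0.023 with called doublets kept and −0.094 at Leiden resolution 2. With the covariate H2-D1 in epithelial-like cells was −0.0077. In macrophage or monocyte-like cells it gave −0.025 for Cxcl10, −0.0069 for Cxcl9 and −0.31 for Spp1. There Cxcl10 was −3.7e-05 with the stricter cell filter and −0.027 with called doublets kept, and Spp1 −0.0088 with the replicate block and −0.018 with called doublets kept.

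Leaving out each library in turn, the count of called genes ranged from 0 to 1 in macrophage or monocyte-like and dendritic-like, 0 to 11 in neutrophil-like, 0 to 9 in T-like, 0 to 10 in NK-like and 1 to 199 in B-like cells. A list counted as reversed when its camera direction changed, so medians that changed sign without this, as for type I interferon in neutrophil-like cells, are left out. Medians of lists that reversed ranged, in all cells, from −0.31 to 0.13 for NF-kB, −0.032 to 0.31 for DNA replication, −0.067 to 0.26 for mitosis and −0.30 to 0.029 for immediate early genes. In epithelial-like cells they ranged from −0.14 to 0.34 for DNA replication and −0.0075 to 0.23 for collagen and matrix, and in macrophage or monocyte-like cells from −0.057 to 0.18 for type I interferon. In dendritic-like cells they ranged from −0.44 to 0.76 for mitosis and −0.18 to 0.36 for alternatively activated macrophage genes, in B-like cells from −0.15 to 0.75 for ribosomal proteins, and in fibroblast-like cells from −0.46 to 0.084 for hypoxia and glycolysis. Differences in shares ranged from −1.35 to 0.700 for B-like, −5.92 to 0.195 for macrophage or monocyte-like, −0.0187 to 0.166 for mast or basophil-like, −0.680 to 10.4 for neutrophil-like and −0.0020 to 0.143 for pericyte-like cells, −3.27 to 3.20 for regulatory T cells and −3.39 to 0.80 for other CD4 cells. Named genes in T-like cells ranged from −0.15 to 0.17 for Foxp3 and −0.0098 to 0.46 for Uhrf1. In epithelial-like cells they ranged from −0.087 to 0.10 for B2m, −0.11 to 0.32 for H2-D1, −0.040 to 0.23 for H2-K1, −0.054 to 0.73 for Irf7, −0.12 to 0.15 for Smyd2, −0.11 to 0.18 for Smyd5 and −0.17 to 0.39 for Uhrf1. In macrophage or monocyte-like cells they ranged from −0.24 to 0.49 for Arg1, −0.19 to 0.25 for Cxcl10, −0.18 to 0.39 for Cxcl9, −0.19 to 0.16 for H2-Ab1, −0.15 to 0.74 for Mrc1 and −0.28 to 0.46 for Spp1.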

Other observations

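Tests chosen only after the results were seen are those on the sex of the mice, on depth per epithelial-like cell, on interferon members held by epithelial-like cells and on the neutrophil share as a covariate.

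Some lists not described above moved in single classes. In neutrophil-like cells MHC class II genes were lower for 6 of 7 members with a median of −0.45 (camera adjusted p = 0.00029, adjusted p = 0.61 with an estimated correlation), but 6 of the 7 are open to free RNA. In B-like cells p53 target genes were higher for 13 of 14 members, with a median of 0.52 (camera adjusted p = 0.0021, adjusted p = 0.27 with an estimated correlation) or 0.32 without Smyd3 ASO replicate 2. Rps27l and Trp53inp1, both induced by p53, had log2 fold changes of 1.68 and 1.53. Ddit4 stood at 24.6 ± 3.7 and 48.0 ± 9.1 CPM in dendritic-like cells (log2 0.96, edgeR adjusted p = 1.0), opposite to its difference in epithelial-like cells. Over all cells Cd40lg, the T cell ligand of CD40, stood at 5.95 and 2.61 CPM (log2 −1.19, edgeR adjusted p = 0.53).

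One structure among the libraries, picked as the division with the most called genes, did not follow the treatment. In epithelial-like cells, control replicates 1 and 2 with Smyd3 ASO replicate 2 differed from the other 3 libraries in 197 genes, against 0 for the real grouping, which points to a structure of the samples. For the other 3 libraries over the former, mitosis genes were lower (median −0.57) and type I interferon genes higher (median 0.48). Free RNA from neutrophils is argued against, as 6.09% of the called genes were under 10% of their neutrophil level. Sex is argued against by a span of 0.352 log2 units for Xist, although 7 UMIs of Ddx3y (0.163 CPM) in control replicate 1 exceeded an earlier bound, which was then widened, and depth by medians that overlap by 2438.5 UMIs. Tumour growth stage, dissection and sequencing run remain untested.

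The higher interferon lists in epithelial-like cells were weighed against free RNA and against a shift between clusters. For free RNA from immune cells, the 8 type I interferon members that epithelial-like cells hold at 50% or more of the highest class were taken. Their median was 0.267 (SD 0.134), with 8 of 8 above 0, which argues against free RNA as the whole cause. Nearly all members of the list were known to be higher when this test was chosen, so the count of 8 adds little. The median lay under the 0.39 of the whole list, so a part from free RNA stays open. A shift between clusters is argued against too, since the lowest median within the 4 clusters was 0.341 for type I interferon (cluster 2) and 0.330 for interferon gamma (cluster 9). The sample structure above may add to the difference, as the type I interferon median was 0.31 with the neutrophil share as a covariate and 0.39 without it. An effect of the Smyd3 ASOs remains a hypothesis that these 6 tumours leave open.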
